A study of Mus musculus with 4 samples.

How the data were processed

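Spleens of mice with acute graft-versus-host disease (aGVHD, the attack of transferred immune cells on the tissues of their host) were profiled by single-cell RNA sequencing. Per the labels' protocols, the spleens came from mice given wild-type or OTUD1-deficient cells, and cDNA libraries were made with the Chromium 3′ v3 kit of 10x Genomics. OTUD1 is a deubiquitinase of the ovarian tumour (OTU) family. The labels give 4 libraries, 2 of the wild-type and 2 of the OTUD1-/- group, all with the strain label Balb/c. They do not say which cells were transferred, how many days passed, which strain the donors had, or whether the 2 libraries of a group come from separate mice or pools. The p-values below therefore measure only the spread between these libraries, which may be technical.

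The deposited files hold, for each library, a matrix of raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 6.0.1, per the file headers. The programs bcl2fastq and Seurat and the genome build mm10 are named per the submitters' processing notes, and the annotation they counted against is not given in the sources used here. Nothing in the values shows a normalization: the deposited counts are whole numbers whose totals differ between libraries, from 98212962 to 125622787 UMIs. The barcodes had been filtered to cells before deposit, with 10456 to 12093 per library. Positions of genes were taken from the GENCODE annotation of GRCm38, the same build as mm10 and possibly another release than the authors used. Of the 32285 gene identifiers in the matrices, 32158 had a position in it.

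Cells with fewer than 300 detected genes (929 of 44417 barcodes) or with over 10% mitochondrial UMIs (868) were left out, which left 42937. Doublets were scored within each library by the scrublet method in scanpy 1.11.5, and the highest scores were removed at a rate of 0.8% per 1000 barcodes, 8.10 to 9.38% of a library and 3699 cells in all. The remaining 39238 cells were clustered together on 2000 variable genes, 30 principal components and 20 neighbours, with the Leiden algorithm (leidenalg 0.10.2) at resolution 1.0. T cell receptor and immunoglobulin segments, mitochondrial, ribosomal and sex-linked genes and Otud1 were kept out of the clustering genes. A cluster took the name of the class with the largest share of its markers raised (by at least 1.0 on the log2 scale and in at least 10% of the cells), if that share reached 25% with at least 3 markers detected. A cluster stayed unnamed where its 10 leading genes held more markers of another class, or several of another class, or where its cells had few UMIs for their library and no marker of the class led. The markers were fixed beforehand and these thresholds were set after the files were seen. Names such as neutrophil stand for neutrophil-like clusters. Of the cells kept, 5822 stayed unnamed, and most of them lay in a cluster of 4884 cells with a median of 650 UMIs. The unnamed share was 17.8% and 21.2% in the wild-type libraries and 13.6% and 6.13% in the OTUD1-/- libraries. A Cd4 T cell was a cell of a T cluster with at least 1 UMI of Cd4 and none of Cd8a or Cd8b1, and a Cd8 T cell the converse.

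Raw counts were summed per library and class, since cells are not replicates, and the genotypes were compared with the quasi-likelihood F test of edgeR 4.0.16 on 2 against 2 summed profiles (TMM factors, filterByExpr, robust fit, Benjamini-Hochberg adjustment over the genes tested, threshold of 0.05). Classes with at least 30 cells in every library were tested. The difference of the genotype effect between Cd8 T and Cd4 T cells was tested as an interaction in 1 fit with the library as a block. The number of cells per class was tested in the same way with all cells kept as library size. Of 38 gene lists, 25 hold genes of pathways and T cell programmes and 13 the markers of cell classes. Lists with at least 5 tested genes were compared with all other genes in Cd4 T and Cd8 T by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists. Shares of T cells with a UMI of Foxp3, Ifng, Tbx21, Mki67, Gzmb, Pdcd1 or a further gene not reported here were counted after thinning each cell to 2000 UMIs, with exact binomial intervals. An exact permutation of 2 against 2 libraries cannot give a two-sided p below 0.333, so no single value was tested that way.

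The groups, tests, lists, markers and alternatives were set before the data were examined, and so was the rule for naming genes. The rule takes Otud1 first. It then takes genes with an adjusted p under 0.05, a mean of at least 10 CPM and both OTUD1-/- libraries on the same side of both wild-type libraries: the 12 largest rises and 12 largest falls in Cd4 T and Cd8 T, and 6 and 6 in other classes. List members that passed are added, up to 4 per list, and where none passed the 5 genes with the smallest p are named as not passing. Immunoglobulin and T cell receptor segments, predicted genes, mitochondrial and ribosomal protein genes are counted but not named by the rule. Leading genes of a cluster are left out of the account of genes within its own class, since they define it. A few genes followed across classes were chosen after their values were seen, and the text says so there.

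The steps were tested on simulated counts with 200 changed genes among the real ones, and this test was first run after the first fits to the real data. In the simulated Cd8 T profiles 28.6% of genes changed 1.5-fold, 67.9% changed 2-fold and 96.8% changed 4-fold were recovered, and in the Cd4 T profiles 5.97%, 48.6% and 82.0%. Of the calls, 21 of 153 in Cd8 T and 14 of 103 in Cd4 T were false, above the nominal share. For the interaction the recovered shares were 2.78%, 23.4% and 82.4%, with 5 false calls of 67. With no list changed, 1 of 33 lists was called in Cd8 T. Genes were simulated independently of one another there. In the real profiles the estimated correlation within a list reached 0.969 (type I interferon response, Cd4 T). This simulation therefore cannot give the share of false calls for lists whose genes move together. In simulated tables of cell numbers a 2.5-fold change of Cd8 T cells was recovered in 15% of 100 tables, and 7% of tables without a change had a call. Of the tables with changes, 13% had an unchanged class called. These tables had 14 classes and a dispersion of 0.103. The real test joined T cells with both and with neither co-receptor and had a dispersion of 0.0785, so its recovered share may differ.

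Alternatives were DESeq2 1.42.0, its size factors within edgeR, no gene filter, looser and stricter cell filters, doublets kept, Leiden resolutions of 0.5 and 2.0, profiles thinned to the smallest total of their class, a gate at 2 UMIs, the replicate number as a block, other denominators of the shares, camera with an estimated correlation, fry, and each library left out in turn. Crossed replicate numbers in Cd4 T, shares without the unnamed clusters and tests of single clusters were added after seeing the data. Libraries of a group were compared before averaging: chi-square per degree of freedom between their summed counts was 2.50 to 34.6, so none was a duplicate within sampling noise.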

Results

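Single-cell libraries were read from the spleens of mice with aGVHD that had received wild-type or OTUD1-deficient cells, with 2 libraries per group. The wild-type libraries held 10838 and 12093 barcodes with 125622787 and 117346803 UMIs, and the OTUD1-/- libraries 10456 and 11030 barcodes with 98212962 and 121379226 UMIs. The median barcode had 8453.5 and 6489 UMIs in the wild-type libraries and 6254.5 and 8296 in the OTUD1-/- libraries. After filtering, 9586 and 10625 wild-type and 9303 and 9724 OTUD1-/- cells remained. Neutrophils made up 31.4% ± 3.54 of wild-type cells (mean ± SD, n = 2 libraries) and monocytes or macrophages 21.1% ± 2.54. Haemoglobin genes took 0.555% and 0.327% of all UMIs in the wild-type libraries and 1.15% and 0.766% in the OTUD1-/- libraries. Immunoglobulin genes took 0.342% and 0.390% against 1.19% and 0.427%.

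Otud1 transcripts were not lower in the libraries labelled OTUD1-/-. Over all cells, Otud1 stood at 1.93 CPM (211 UMIs) and 1.08 CPM (109 UMIs) in the wild-type libraries and at 2.10 CPM (183 UMIs) and 1.98 CPM (210 UMIs) in the OTUD1-/- libraries. Cd4 T cells had 3.98 and 4.78 CPM against 5.75 and 3.46, and Cd8 T cells 1.34 and 1.93 against 1.55 and 2.11. Monocytes or macrophages had 3.74 and 1.97 CPM against 4.34 and 3.43, and progenitors 2.01 and 2.43 against 1.79 and 3.08. Fewer UMIs lay behind the other classes. Neutrophils had 0.171 and 0.182 CPM against 0.191 and 0.302, erythroid cells 3.02 and 2.83 against 1.08 and 2.05, and conventional dendritic cells 0.883 and 1.64 against 6.91 and 2.34. Basophils had 1.07 and 1.90 CPM against 0 and 0.752, plasma cells 2.54 and 0 against 0.867 and 0, and platelets or megakaryocytes 0 and 0 against 2.91 and 0. B cells held 1 and 1 Otud1 UMIs in the wild-type and 6 and 2 in the OTUD1-/- libraries. The edgeR log2 fold change was 0.02 (SE 0.44, adjusted p = 0.990) in Cd4 T, 0.21 (SE 0.36, adjusted p = 0.891) in Cd8 T, 0.22 (SE 0.53, adjusted p = 0.881) in progenitors and 0.39 (SE 0.34, adjusted p = 0.832) in monocytes or macrophages.

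Otud1 (ENSMUSG00000043415) is a gene of 1 exon on the plus strand of chromosome 2, from 19657752 to 19660583 on GRCm38. Its coding sequence runs from 19658062 to 19659423 and is followed by a 3′ UTR of 1160 bp. A 3′ kit reads the end of the transcript, and the labels do not describe the deleted part. A transcript that keeps its 3′ end would be counted here although no protein is made, so these counts check neither the deletion nor the labels. The labels also say that cells were transferred, and host cells carry the gene whatever the donor genotype. The group is therefore called by its label throughout.

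**Figure D1:**
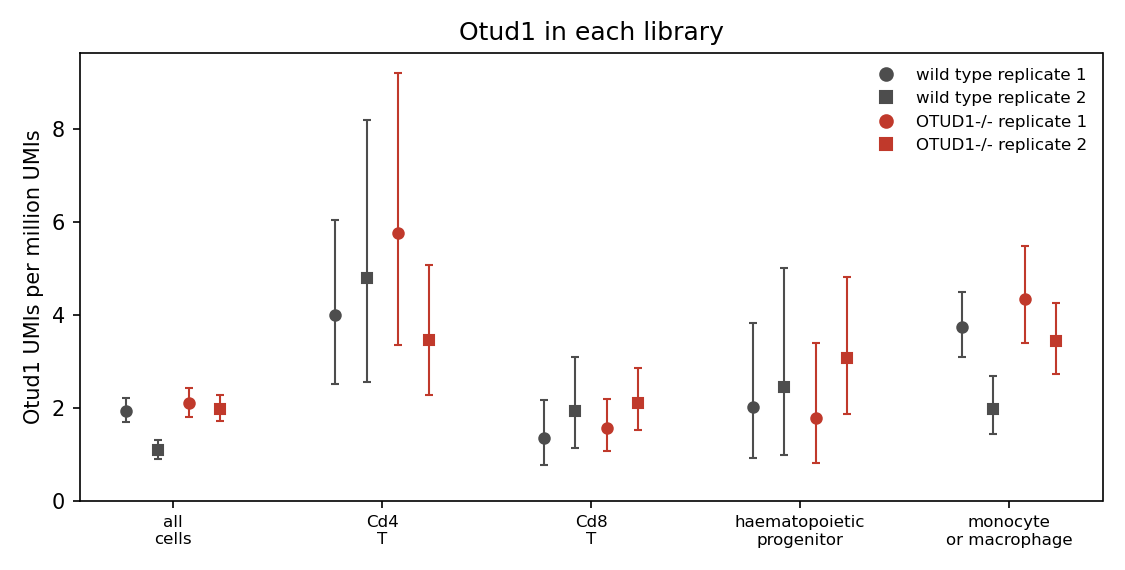
Otud1 level in CPM (vertical axis) in each of the 4 libraries for all cells and for classes with enough UMIs, with exact Poisson 95% intervals as bars that cover counting error only. The wild-type libraries lie at 1.93 and 1.08 CPM over all cells and those labelled OTUD1-/- at 2.10 and 1.98 CPM.

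The makeup of the spleen differed between the groups. Cd8 T cells rose from 9.50% ± 0.817 of cells in the wild-type libraries to 21.9% ± 1.73 in the OTUD1-/- libraries (n = 2 each), a log2 fold change of 1.21 (SE 0.42, edgeR adjusted p = 0.0251). Erythroid cells rose from 2.89% ± 1.54 to 7.36% ± 0.892 (log2 1.35, SE 0.42, adjusted p = 0.0229) and antibody-secreting plasma cells from 0.550% ± 0.0190 to 1.34% ± 0.614 (log2 1.28, SE 0.44, adjusted p = 0.0251). B cells were rare in every library and rose from 0.0553% ± 0.0250 to 0.427% ± 0.0951 (log2 2.94, SE 0.58, adjusted p = 0.000397), from 7 and 4 cells to 46 and 35 cells. With predicted doublets kept the log2 fold change of B cells was 1.63 (adjusted p = 0.0217), and without wild-type 2 it was 2.53 (adjusted p = 0.162). In each of these 4 classes both OTUD1-/- libraries lay above both wild-type libraries. Chance sets 2 libraries apart from 2 others, in either direction, in 33.3% of cases.

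The other classes did not pass. Cd4 T cells were 4.91% ± 1.90 and 6.60% ± 2.40 of cells (adjusted p = 0.405), neutrophils 31.4% ± 3.54 and 26.3% ± 5.35 (adjusted p = 0.542) and monocytes or macrophages 21.1% ± 2.54 and 16.3% ± 0.159 (adjusted p = 0.431). Conventional dendritic cells were 3.51% ± 0.172 and 2.74% ± 0.428 (adjusted p = 0.431), basophils 2.19% ± 0.632 and 1.24% ± 0.318, progenitors 1.02% ± 0.186 and 1.80% ± 0.308, and T cells with both or neither co-receptor 1.68% ± 0.654 and 3.03% ± 0.671 (adjusted p = 0.108 for each). Platelets or megakaryocytes were 1.66% ± 0.957 and 1.02% ± 0.181 (adjusted p = 0.167). The unnamed cells, 19.5% ± 2.37 and 9.85% ± 5.26 (adjusted p = 0.0638), are mostly barcodes with few UMIs and weigh on every other share. With them left out of the denominator, 2 classes passed, and Cd8 T cells (log2 1.05) and plasma cells (log2 1.14) had an adjusted p of 0.0501. The 4 calls became 1 with TMM factors on the cell numbers, and 1, 0, 1 and 1 without wild-type 1, wild-type 2, OTUD1-/- 1 and OTUD1-/- 2. The log2 fold change of Cd8 T cells then lay between 1.12 and 1.30 and that of erythroid cells between 0.89, without wild-type 2, and 2.03, without wild-type 1.

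**Figure D2:**
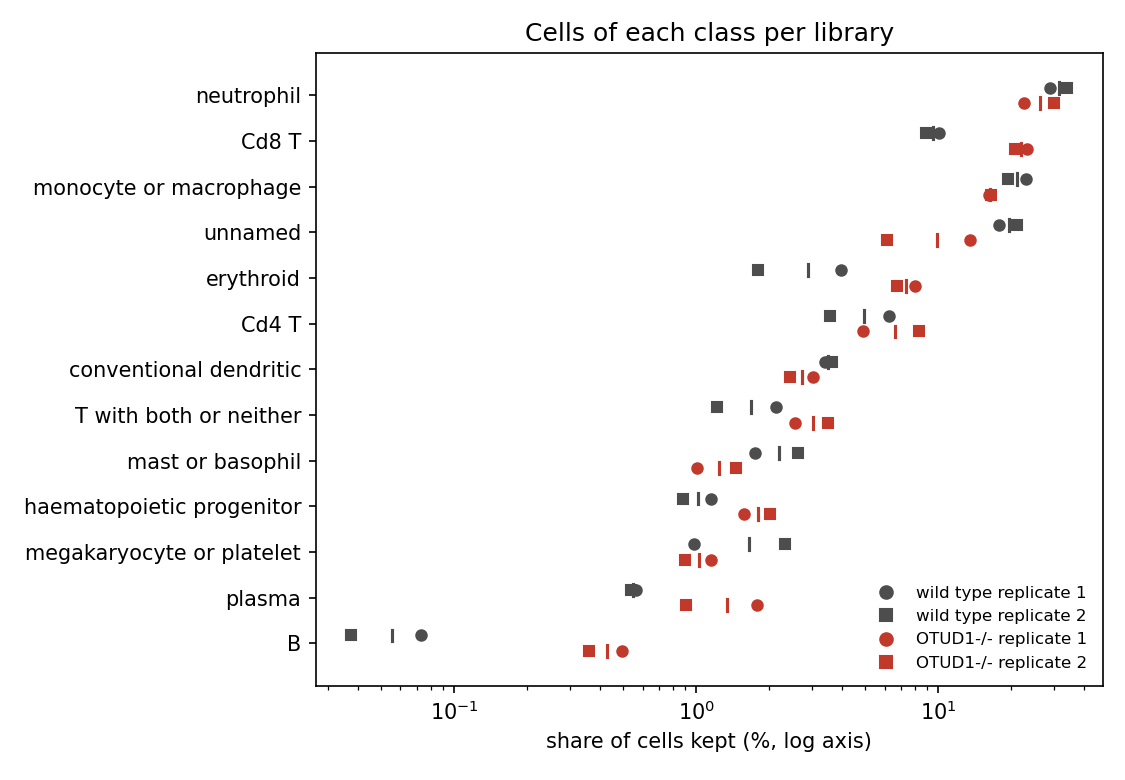
Share of each cell class in percent of the cells kept (log axis), with 1 point per library, groups in separate colours and a tick at each group's mean. Cd8 T cells lie at 10.1% and 8.92% in the wild-type and at 23.2% and 20.7% in the OTUD1-/- libraries, and B, erythroid and plasma cells are also higher in both OTUD1-/- libraries.

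In Cd8 T cells 4 of 13557 genes passed the comparison of OTUD1-/- with wild-type libraries, 2 higher and 2 lower. Ifi208 (ENSMUSG00000066677), a member of the interferon-inducible Ifi200 family, fell from 91.0 and 82.6 CPM to 3.74 and 2.35 (log2 -4.83, SE 0.20, edgeR adjusted p = 0.000221). Hhat (ENSMUSG00000037375), the enzyme that attaches palmitate to Hedgehog proteins, fell from 41.8 and 42.1 to 13.3 and 12.2 CPM (log2 -1.71, SE 0.12, adjusted p = 0.00388). Camk2b (ENSMUSG00000057897), a subunit of a calcium- and calmodulin-dependent kinase, rose from 11.5 and 10.8 to 43.4 and 34.9 CPM (log2 1.81, SE 0.15, adjusted p = 0.0122). The other gene that rose, Gm42031, is a predicted gene that lies outside the naming rule and was named after its values were seen (log2 3.68, SE 0.22, adjusted p = 0.00228). On GRCm38, Ifi208 spans 173673675 to 173698395 and Hhat 192496711 to 192771223 of chromosome 1, and Camk2b 5969644 to 6066362 of chromosome 11. The Ifi200 genes resemble one another, so reads of Ifi208 shared with a relative could be left uncounted.

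The cells behind this comparison numbered 966 and 948 in the wild-type and 2156 and 2015 in the OTUD1-/- libraries, with 8792579 to 21223818 UMIs per summed profile. At an unadjusted p under 0.05 stood 1087 genes, and DESeq2 called 75 (21 higher, 54 lower). The count was 56 without a gene filter, and 42, 4, 175 and 312 without wild-type 1, wild-type 2, OTUD1-/- 1 and OTUD1-/- 2, where the lone library is assumed to vary like the other group. Without wild-type 2 the call of Camk2b ended (adjusted p = 0.0720).

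In Cd4 T cells no gene of 11410 passed with edgeR, while 812 had an unadjusted p under 0.05 and DESeq2 called 22 (13 higher, 9 lower). Of the 5 genes with the smallest p among those the rule allows to be named, none passed, and 3 are those named in Cd8 T. Ifi208 stood at 102 and 99.2 CPM in the wild-type and 10.0 and 2.78 in the OTUD1-/- libraries (log2 -4.24, SE 0.47, adjusted p = 0.230) and Hhat at 31.6 and 45.04 against 12.8 and 11.5 (log2 -1.65, SE 0.24, adjusted p = 0.230). Camk2b had 11.6 and 14.9 against 51.8 and 41.4 CPM (log2 1.83, SE 0.22, adjusted p = 0.148). Id3, an inhibitor of E proteins that is high in naive and memory precursor T cells, had 8.81 and 9.08 against 32.5 and 31.2 CPM (log2 1.83, SE 0.21, adjusted p = 0.148). Nbea had 0.367 and 0.726 against 11.7 and 8.59 CPM (log2 4.26, SE 0.54, adjusted p = 0.148). The cells numbered 599 and 379 against 456 and 806, with 2718642 to 7509465 UMIs per profile. The count of 0 was 211 without a gene filter, and 0, 1, 471 and 127 without wild-type 1, wild-type 2, OTUD1-/- 1 and OTUD1-/- 2.

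In Cd4 T cells the Th1 list, genes of interferon-gamma-producing helper cells, fell as a list in the OTUD1-/- libraries: 12 of 14 tested members lay below 0, with a median log2 fold change of -0.32 (camera adjusted p = 0.000425, adjusted p = 0.524 with an estimated correlation). Il18rap, a receptor chain for interleukin 18, stood at 304 and 251 against 205 and 169 CPM (log2 -0.58, SE 0.17) and Ifng at 78.2 and 87.9 against 72.9 and 35.3 (log2 -0.65, SE 0.33). The most abundant members, the chemokine Ccl5 and the transcription factor Stat4, had log2 values of -0.24 (SE 0.33) and -0.15 (SE 0.18). Oxidative phosphorylation genes rose as a list (19 of 19 above 0, median 0.32, adjusted p = 2.72e-06, 0.524 with an estimated correlation), with Cox4i1 at 0.30 (SE 0.18) and Cox6c at 0.36 (SE 0.17). Immediate early and stress genes fell (11 of 14 below 0, median -0.28, adjusted p = 0.000425, 0.524 with an estimated correlation), among them Hspa8, a constitutive chaperone, at -0.60 (SE 0.16), the phosphatase Dusp1 at -1.36 (SE 0.32) and Fos at -1.12 (SE 0.31). Adjusted over the list alone, these 3 of 14 passed, and 0 Th1 and 0 oxidative phosphorylation genes did. Adjusted over all genes, no member of any list passed in Cd4 T or Cd8 T with edgeR, where 812 and 1087 genes had an unadjusted p under 0.05 and DESeq2 called 22 and 75.

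Exhaustion and inhibitory receptor genes also fell in Cd4 T cells (9 of 13 below 0, median -0.34, adjusted p = 0.00254, 0.524 with an estimated correlation). The ectonucleotidase Entpd1 at -0.80 (SE 0.15), the nuclear receptor Nr4a2 at -1.05 (SE 0.23) and the inhibitory receptors Havcr2 at -1.21 (SE 0.31) and Lag3 at -0.87 (SE 0.24) passed when adjusted over the list alone (4 of 13). Type I interferon response genes were called with 20 of 20 below 0 (median -0.41, adjusted p = 4.24e-07, 0.524 with an estimated correlation), for example Ifi27l2a at 4164 and 3358 against 4452 and 2090 CPM (log2 -0.20, SE 0.36) and Bst2 at 360 and 228 against 278 and 109 (log2 -0.62, SE 0.50). Interferon gamma response genes had 16 of 19 below 0 (median -0.31, adjusted p = 0.000419, 0.566 with an estimated correlation). Cell cycle genes had 22 of 23 above 0 (median 0.31, adjusted p = 0.0135, 0.682 with an estimated correlation), with Mki67 at 435 and 362 against 325 and 694 CPM. Adjusted over the list alone, 0 genes of the last 3 lists passed. Without OTUD1-/- 2 the adjusted p was 0.109 for exhaustion and for type I interferon and 0.624 for interferon gamma, and the cell cycle list turned to lower with 3.24e-05. Without wild-type 1 it was 0.0771 for exhaustion and 0.0795 for interferon gamma, and without wild-type 2 it was 0.453 for the cell cycle.

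Further lists called lower in Cd4 T cells were Th17 (median -0.38, 8 of 9 below 0, adjusted p = 0.0135), T cell receptor activation (-0.20, 12 of 17, 0.0135), cytotoxicity (-0.25, 9 of 13, 0.0158), apoptosis (-0.22, 12 of 16, 0.0183), homing and chemokine receptors (-0.16, 11 of 15, 0.00642), Notch (-0.14, 14 of 17, 0.0225), OTU deubiquitinases (-0.13, 9 of 12, 0.0450) and myeloid cytokines (-0.45, 4 of 6, 0.0225). With an estimated correlation their adjusted p was 0.524, or 0.528 for the OTU deubiquitinases. Adjusted over the list alone, Slamf1 at -0.76 (SE 0.14) passed in the T cell receptor list and the pro-apoptotic Bcl2l11 at -0.69 (SE 0.17) in the apoptosis list, 1 gene each, and 0 genes of the other lists did. Each of these 8 calls ended without OTUD1-/- 2, with adjusted p from 0.0686 for cytotoxicity to 0.909 for myeloid cytokines. Without wild-type 1 those of T cell receptor activation (0.0543), cytotoxicity (0.260), apoptosis (0.108), homing (0.109) and OTU deubiquitinases (0.0582) ended, and without wild-type 2 those of Th17 (0.115), Notch (0.216) and OTU deubiquitinases (0.198). Not called were regulatory T genes (median -0.23, adjusted p = 0.0503), naive and central memory genes (0.28, 0.0525), NF-kB (-0.10, 0.260), glycolysis (0.08, 0.973), the unfolded protein response (-0.02, 0.491) and MHC class II (-0.01, 0.571). Of the 20 lists called in Cd4 T, 4 higher and 16 lower, none was called with an estimated correlation or by fry. Of these calls 13, 15, 20 and 7 were kept without wild-type 1, wild-type 2, OTUD1-/- 1 and OTUD1-/- 2, and 6 in all 4 cases, among them Th1, stress and oxidative phosphorylation.

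Markers of other cells moved with these lists in Cd4 T. Neutrophil markers were lower (median -0.79, 15 of 16 below 0, adjusted p = 7.85e-08, 0.524 with an estimated correlation), with S100a8 at 1348 and 2700 against 909 and 1108 CPM. Monocyte or macrophage markers were lower (median -0.56, 17 of 17, adjusted p = 7.38e-08) and plasmacytoid dendritic markers too (-0.41, 5 of 5, 0.00403). Erythroid markers (0.80, 12 of 12, adjusted p = 1.84e-05) and the haemoglobin list (0.82, 8 of 8, 0.000768) were higher. Each had an adjusted p of 0.524 with an estimated correlation. Adjusted over the list alone, 6 monocyte or macrophage markers passed, among them Fcgr1 at -1.31 (SE 0.34) and F13a1 at -0.94 (SE 0.25), and 2 plasma markers, Jchain at 1.43 (SE 0.33) and Prdm1 at -0.54 (SE 0.17). The call of the plasmacytoid markers ended without OTUD1-/- 2 (adjusted p = 0.377) and that of the haemoglobin list without wild-type 2 (0.453). Markers of T cells (0.10, adjusted p = 0.134), plasma cells (-0.13, 0.932, with the test upward) and conventional dendritic cells (0.55, 0.260) were not called. Lists with under 5 tested genes were not tested: their medians were -0.34 for Th2, -0.47 for NK or ILC, 1.17 for B, -0.03 for megakaryocyte or platelet, -0.36 for mast or basophil, -0.19 for progenitor and -0.04 for stromal or endothelial markers.

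In Cd8 T cells, genes induced by T cell receptor activation fell as a list (14 of 17 below 0, median -0.25, adjusted p = 5.61e-05, 0.608 with an estimated correlation). The early response transcription factors Nr4a3 at -1.59 (SE 0.25), Egr3 at -1.51 (SE 0.29) and Egr2 at -0.89 (SE 0.19) and the receptor Slamf1 at -0.47 (SE 0.13) passed when adjusted over the list alone (4 of 17). Stress genes fell (13 of 16, median -0.40, adjusted p = 2.72e-05, 0.608 with an estimated correlation), with Hspa8 at -0.65 (SE 0.15), Dusp1 at -0.88 (SE 0.18) and the inducible chaperone Hspa1b at -2.41 (SE 0.62) passing over the list alone (3 of 16). Cytotoxicity genes fell by little as a list (11 of 15, median -0.08, adjusted p = 0.0171, 0.608 with an estimated correlation). Adjusted over the list alone, 6 of 15 passed: the killing effectors Prf1 at -0.69 (SE 0.17), Gzmb at -0.51 (SE 0.16), Gzmk at -0.47 (SE 0.12) and Fasl at -0.44 (SE 0.11) and the granzyme inhibitor Serpinb9 at -0.39 (SE 0.11) were lower, and the receptor chain Klrd1 at 0.62 (SE 0.13) was higher. The unfolded protein response fell (15 of 16, median -0.25, adjusted p = 3.82e-05, 0.608 with an estimated correlation), with Hspa5 at -0.38 (SE 0.14).

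Type I interferon (20 of 20 below 0, median -0.29, adjusted p = 3.27e-05, 0.647 with an estimated correlation) and interferon gamma response genes (18 of 20, -0.23, 2.72e-05, 0.624) were called lower in Cd8 T cells too. Without OTUD1-/- 2 their adjusted p was 0.274 and 0.287. Lower calls came further for NF-kB (median -0.11, 16 of 18, adjusted p = 0.00350), Notch (-0.10, 13 of 18, 0.0389) and myeloid cytokines (-0.38, 8 of 10, 0.0389), and a higher one for oxidative phosphorylation (0.19, 18 of 19, 0.000250). With an estimated correlation their adjusted p was 0.608, 0.619, 0.608 and 0.647. The call of NF-kB ended without OTUD1-/- 1 (adjusted p = 0.0779), and that of oxidative phosphorylation without OTUD1-/- 1 (0.196) and wild-type 2 (0.234). The call of Notch ended without wild-type 1 (0.0557), wild-type 2 (0.183) and OTUD1-/- 1 (0.617), and that of myeloid cytokines without wild-type 2 (0.183) and OTUD1-/- 2 (0.690). Notch1 at -0.46 (SE 0.10) passed over its list alone. Not called were Th1 (median 0.06, adjusted p = 0.755), Th2 (-0.08, 0.498), Th17 (-0.13, 0.307), regulatory T (-0.06, 0.919), exhaustion (0.07, 0.908, with the test downward), naive (0.18, 0.498), cell cycle (0.10, 0.498), glycolysis (-0.02, 0.345), apoptosis (-0.11, 0.0693), homing (0.02, 0.923, with the test downward), OTU deubiquitinases (-0.07, 0.295) and MHC class II (-0.07, 0.923, with a mean of 0.03). Over their lists alone Entpd1 at -0.76 (SE 0.13), the transcription factor Maf at -0.70 (SE 0.11) and the chemokine receptor Cxcr4 at -0.91 (SE 0.15) passed.

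Beside these lists stood the markers of other cells in Cd8 T. Neutrophil markers (16 of 16 below 0, median -0.77, adjusted p = 9.81e-09), monocyte or macrophage markers (18 of 18, -0.53, 3.88e-10) and mast or basophil markers (8 of 9, -0.56, 0.0104) were lower. Erythroid markers (12 of 14 above 0, 0.33, 0.00536), the haemoglobin list (7 of 9, 0.27, 0.0389) and B cell markers (6 of 6, 0.47, 0.0389) were higher. With an estimated correlation the adjusted p was 0.608 to 0.641. Without wild-type 1 or OTUD1-/- 1 the erythroid (adjusted p = 0.326 and 0.196) and haemoglobin calls (0.468 and 0.859) ended. The basophil call ended without wild-type 2 (0.116) or OTUD1-/- 1 (0.313), and the B cell call without wild-type 1 (0.0557), wild-type 2 (0.183) or OTUD1-/- 2 (0.268). Over the list alone 6 neutrophil and 6 macrophage markers passed, for example S100a8 at -1.02 (SE 0.25) and C1qc at -0.55 (SE 0.11). So did the B cell factor Ebf1 at 2.59 (SE 0.50), the plasma markers Mzb1 at 2.55 (SE 0.46), Iglv1 at 2.01 (SE 0.53) and Jchain at 0.82 (SE 0.20), the NK markers Klre1 at 0.99 (SE 0.24) and Tyrobp at -0.62 (SE 0.14), and Cdk6 of the progenitor markers at -0.50 (SE 0.14). T markers (0.10, adjusted p = 0.371), NK or ILC (-0.16, 0.794), plasma (0.67, 0.0909), conventional dendritic (-0.06, 0.498) and plasmacytoid dendritic markers (-0.12, 0.680) were not called. Medians of untested lists were -0.69 for megakaryocyte or platelet, -0.32 for progenitor and -0.13 for stromal or endothelial markers. Of the 16 lists called, 4 higher and 12 lower, 12, 11, 10 and 12 kept their call without wild-type 1, wild-type 2, OTUD1-/- 1 and OTUD1-/- 2, and 6 kept it in all 4 cases. None was called with an estimated correlation or by fry.

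**Figure D3:**
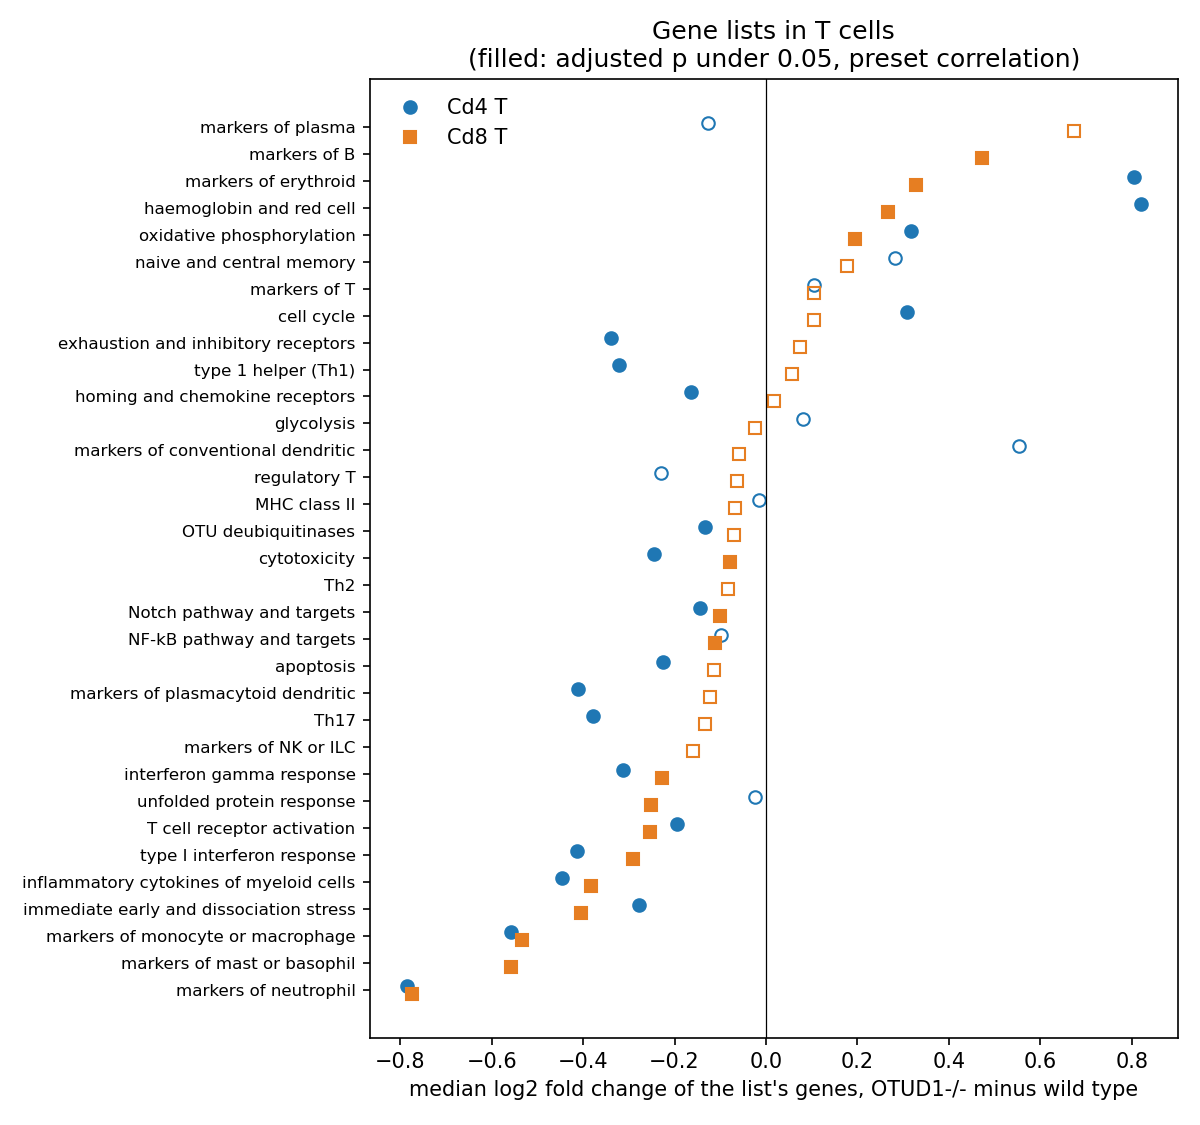
Median log2 fold change of each tested list, OTUD1-/- minus wild type (horizontal axis), in Cd4 T and Cd8 T cells, with filled points for lists called by camera with the preset correlation. Type I interferon genes lie at -0.41 and -0.29, neutrophil markers at -0.79 and -0.77 and oxidative phosphorylation genes at 0.32 and 0.19, and no list was called with an estimated correlation.

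Lists of strain- and sex-linked genes served as checks of the samples. Of the strain reporters only Ighg2c, an immunoglobulin constant region carried by some strains, was measured in T cells: 16.0 and 60.7 against 226 and 274 CPM in Cd4 T (log2 2.78, SE 0.67, adjusted p = 0.637) and 15.3 and 52.2 against 209 and 82.2 in Cd8 T (log2 2.13, SE 0.72, adjusted p = 0.605). Plasma cells, the source of immunoglobulin transcripts, were more frequent in the OTUD1-/- libraries. Ighg2c was higher in all 10 classes tested, plasma cells among them (log2 0.82 to 2.78). Another constant region, Igha, looked at after its values were seen, was lower in all 7 classes tested (-2.55 to -1.32). The frequency of plasma cells alone does not account for both, and what else moved them was not tested. Xist, expressed from the inactive X chromosome, stood at 700 and 822 against 740 and 745 CPM in Cd8 T (log2 -0.04, SE 0.14).

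The genotype effect was not shown to differ between Cd8 T and Cd4 T cells for any gene. The interaction test of edgeR called 0 of 12999 genes, with 425 at an unadjusted p under 0.05, and DESeq2 called 0. The 2 smallest p-values belonged to Tprg (difference in log2 fold change 1.52, SE 0.22, adjusted p = 0.826) and the calcium channel gene Cacna1d (1.20, SE 0.20, adjusted p = 0.826). The inhibitory receptor Lag3, chosen after its values were seen, was at -0.87 in Cd4 T and -0.10 in Cd8 T, a difference of 0.77 (SE 0.16, adjusted p = 0.826). The count was 44 without a gene filter, and 11, 1, 460 and 194 without wild-type 1, wild-type 2, OTUD1-/- 1 and OTUD1-/- 2.

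Of the T cell state genes, Gzmb, the gene of granzyme B, had a UMI in 47.4% and 46.9% of wild-type Cd8 T cells and in 45.2% and 32.8% of OTUD1-/- Cd8 T cells, after thinning to 2000 UMIs. In Cd4 T cells Ifng was seen in 13.3% and 10.7% against 9.91% and 6.78%, the Th1 regulator Tbx21 in 27.2% and 24.5% against 19.4% and 21.5%, and the inhibitory receptor Pdcd1 in 32.2% and 28.8% against 25.9% and 22.5%. Tbx21 in Cd8 T cells was at 30.3% and 31.1% against 26.3% and 29.5%, and Pdcd1, alone in that direction, at 32.3% and 31.0% against 32.9% and 33.6%. These 6 of 14 pairs of gene and class had libraries that did not overlap, 5 lower and 1 higher, where chance gives 33.3%. In CPM of the summed profiles, 39.9% of all tested genes in Cd4 T and 40.2% in Cd8 T had libraries apart. The proliferation gene Mki67, Gzmb in Cd4 T, Ifng in Cd8 T and the regulatory T cell factor Foxp3 in both overlapped, with Foxp3 in under 1% of cells (0.0475% to 0.939%). In erythroid cells, which should lack them, Ifng, Tbx21, Gzmb and Pdcd1 were seen in 0 to 2.29% of cells. The median depth before thinning, over the cells with at least 2000 UMIs, was 5783.5 to 8455 UMIs in Cd4 T, 7961 to 10147.5 in Cd8 T and 4250 to 5475.5 in erythroid cells. Thinning left out 6, 4, 12 and 9 Cd4 T cells, 8, 20, 52 and 19 Cd8 T cells and 119, 60, 233 and 158 erythroid cells.

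Without thinning the mean share of Gzmb in Cd8 T cells was 71.0% and 60.4%, that of Ifng in Cd4 T 27.6% and 22.8%, that of Tbx21 58.3% and 50.3% in Cd4 T and 70.3% and 66.1% in Cd8 T, and that of Pdcd1 60.1% and 52.9% in Cd4 T and 69.9% and 69.3% in Cd8 T. Then 3 of the 14 pairs stood apart, but of the 6 above only Gzmb in Cd8 T, and the others overlapped. At 1000 UMIs 2 did, Gzmb in Cd8 T and Tbx21 in Cd4 T. An exact permutation test of 2 against 2 libraries cannot give a p below 0.333.

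Outside the T cells, 539 genes were called over 8 classes, 164 higher and 375 lower in the OTUD1-/- libraries, each class being tested on its own. The total was 3965 without a gene filter, and 2767, 1176, 1163 and 1521 without wild-type 1, wild-type 2, OTUD1-/- 1 and OTUD1-/- 2.

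In conventional dendritic cells 253 of 9242 genes were called (82 higher, 171 lower). Dtx1, an E3 ligase of the Notch pathway, rose from 16.9 and 10.4 to 55.4 and 56.5 CPM (log2 2.04, SE 0.30, edgeR adjusted p = 0.00282), and the Notch coactivator Maml3 rose as well (1.00, SE 0.19, 0.00990). Il12rb2, a chain of the interleukin 12 receptor, rose (1.33, SE 0.28, 0.0186), and so did Klrd1 (1.30, SE 0.26, 0.0142) and the coiled-coil gene Ccdc192 (3.71, SE 0.55, 0.00301). Lower were Ifi208 (-4.46, SE 0.48, 0.000225), the inhibitory receptor Btla (-1.04, SE 0.17, 0.00514), the transcription factor Maf (-1.23, SE 0.25, 0.0168), Serpinb9 (-1.23, SE 0.18, 0.00315), Cd8a (-1.25, SE 0.24, 0.0144), the NF-kB inhibitor Nfkbia (-1.07, SE 0.21, 0.0141) and Hspa8 (-0.93, SE 0.12, 0.00117). Markers of other cells went both ways in the same class: the neutrophil granule gene Camp fell from 1346 and 1916 to 190 and 266 CPM (-2.84, SE 0.21, 0.000157), Ngp, Ltf and Lcn2 fell by 2.36, 2.51 and 2.34, and the macrophage genes Vcam1 and C1qc fell by 1.41 and 1.34 on the log2 scale. Higher were Adgre1 of the macrophage list (1.12, SE 0.23, 0.0198), Cd22 of the B list (1.498, SE 0.36, 0.0398), Klrb1f of the NK or ILC list (1.74, SE 0.43, 0.0462), Runx2 of the plasmacytoid dendritic list (1.00, SE 0.23, 0.0434) and Tfrc of the erythroid list (1.26, SE 0.26, 0.0193).

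The mix of the dendritic class differed between libraries. Its cluster led by Xcr1 and Clec9a held 286 and 332 of the 325 and 386 wild-type and 200 and 153 of the 283 and 237 OTUD1-/- cells. Tested alone, this cluster gave 5 calls (5 higher, 0 lower; 457 genes at an unadjusted p under 0.05) and the smaller one, with 39 cells or more per library, 120 (28 higher, 92 lower). At an unadjusted p under 0.05 stood 1374 genes of the whole class, DESeq2 called 151, and the count was 107 with the strict cell filter, 471 with doublets kept, and 555, 461, 391 and 261 without wild-type 1, wild-type 2, OTUD1-/- 1 and OTUD1-/- 2. Of the 42 named genes of this class, 13 kept their call in every other setting, 22 without each library and 9 in both.

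In erythroid cells 124 of 10008 genes were called (22 higher, 102 lower). Btaf1, a remover of the TATA-binding protein from DNA, rose from 152 and 141 to 377 and 395 CPM (log2 1.39, SE 0.15, edgeR adjusted p = 0.00179). Among the genes that fell were Fcnb, a ficolin of granulocytes (-2.28, SE 0.22, 0.00152), and the macrophage genes C1qa (-1.67, SE 0.19, 0.00314), C1qc (-1.58, SE 0.19, 0.00415) and Vcam1 (-1.64, SE 0.21, 0.00459), all 3 of which stand in the macrophage marker list. These 5 kept their calls without each library. The histone genes Hist1h2ai (1.38), Hist1h2bn (1.35) and Hist2h2ac (1.25) rose, calls that ended without OTUD1-/- 1 (adjusted p = 0.209, 0.158 and 0.0914). Without that library 17 genes were called, and 942, 367 and 154 without wild-type 1, wild-type 2 and OTUD1-/- 2. With doublets kept the count was 3, and at resolution 0.5 it was 2. Over 10 other settings, Btaf1 kept its call in 9, and Fcnb, C1qa, C1qc and Vcam1 in 7 each. Of the 20 named genes of this class, 0 kept their call in every other setting. The mix of the class differed between libraries: its cluster led by Hemgn, Sptb and Ank1 held 79 and 22 wild-type and 221 and 159 OTUD1-/- cells, and that led by haemoglobin genes 77 and 55 against 78 and 101. Shares of single clusters were tested after the results were seen. That of the Hemgn cluster passed (log2 1.96, SE 0.54, edgeR adjusted p = 0.00812). That of the haemoglobin cluster did not (0.51, SE 0.53, 0.506). Tested alone, the 3 clusters with enough cells gave 1, 2 and 2 calls, so the changes of the whole class are not shown to lie within its cells rather than in their mix.

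In progenitors 51 of 11333 genes were called (13 higher, 38 lower). Zbtb16, the transcription factor PLZF, fell from 23.5 and 25.4 to 2.31 and 4.18 CPM (log2 -2.86, SE 0.29, edgeR adjusted p = 0.0126). Fkbp5, a co-chaperone of the glucocorticoid receptor that is itself induced by glucocorticoids, fell from 195 and 211 to 78.0 and 75.1 CPM (-1.41, SE 0.11, 0.00346). Both kept their calls in every setting. The other 13 named genes lost theirs without wild-type 2, among them the cyclin gene Ccnd1 (-1.49, adjusted p = 0.0857 without it) and the stem cell factor receptor Kit (-0.65, 0.1301), which fell, and the Rh antigen gene Rhd (0.71, 0.139), which rose. The count was 143, 24, 283 and 913 without wild-type 1, wild-type 2, OTUD1-/- 1 and OTUD1-/- 2, and 11 with doublets kept. DESeq2 called 107.

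Basophils had 56 called genes of 9648 (31 higher, 25 lower). The immediate early factor Egr1 rose from 24.4 and 33.4 to 108 and 107 CPM (log2 1.87, SE 0.20, edgeR adjusted p = 0.000933), the histone gene Hist1h2bc rose (1.60, SE 0.15, 0.000408) and so did the MHC class II gene H2-Eb1 (1.19, SE 0.21, 0.0196). The tight junction gene Cldn1 (-2.29, SE 0.32, 0.00534), Ifi27l2b (-2.04, SE 0.27, 0.00429), Gmds of fucose synthesis (-1.48, SE 0.19, 0.00429) and the endoplasmic reticulum chaperone Hspa5 (-0.82, SE 0.13, 0.0139) fell. Interferon-induced Ifit3, Isg15, Rsad2 and Oas3 fell by 2.30, 1.46, 1.21 and 1.00, and their calls ended without OTUD1-/- 2 (adjusted p = 0.0740, 0.0757, 0.196 and 0.0740). The monocyte marker Ly6c2 fell by 0.88 (SE 0.15). The count was 24 with doublets kept, 32 after thinning, 27 by DESeq2, and 237, 107, 206 and 57 without wild-type 1, wild-type 2, OTUD1-/- 1 and OTUD1-/- 2.

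In platelets or megakaryocytes 8 of 5311 genes were called (1 higher, 7 lower). Tox, a transcription factor of the HMG box family, rose from 124 and 123 to 619 and 547 CPM (log2 2.24, SE 0.24, edgeR adjusted p = 0.00758). Its call was kept in 6 of 10 other settings. Tox was also measured in T cells (log2 -0.34 in Cd4 T and 0.12 in Cd8 T). Whether RNA of T cells adds to its rise here was not tested. Igfbp5, which binds insulin-like growth factors, stood at 108 and 79.3 CPM in the wild-type libraries and had no UMI in the OTUD1-/- libraries (adjusted p = 0.0123), and the matrix gene Dcn, a stromal marker, at 103 and 50.9 CPM against 0 (adjusted p = 0.0349). The interferon-induced GTPase Iigp1 fell from 243 and 247 to 54.1 and 61.6 CPM (-2.07, SE 0.28, 0.0164), a call that ended without OTUD1-/- 1 (adjusted p = 0.0506), and its direction turned with the strict cell filter (0.12). The calls of Dcn ended without OTUD1-/- 1 (adjusted p = 0.140) or OTUD1-/- 2 (0.0652). The count was 65, 74, 3 and 26 without wild-type 1, wild-type 2, OTUD1-/- 1 and OTUD1-/- 2, and 0 with edgeR under the loose cell filter, against 588 genes at an unadjusted p under 0.05 and 7 by DESeq2 under the standard filter.

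Monocytes or macrophages had 5 called genes of 13664 (3 higher, 2 lower). Tested alone, the clusters of this class with enough cells gave more, 19, 23, 30 and 31 calls. The few calls of the whole class therefore do not show that its cells hardly changed. Ifi208 fell from 41.7 and 47.7 to 0.306 and 0.531 CPM (log2 -6.66, SE 0.23, edgeR adjusted p = 6.68e-05) and Fkbp5 from 438 and 430 to 169 and 189 CPM (-1.28, SE 0.12, 0.0236). The 3 genes that rose, Gm42031, Gm43305 and Gm49980, are predicted genes named after their values were seen (log2 3.32, SE 0.13; 1.57, SE 0.12; 1.80, SE 0.17). DESeq2 called 94, and the count was 131, 9, 131 and 20 without wild-type 1, wild-type 2, OTUD1-/- 1 and OTUD1-/- 2.

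In neutrophils 10 of 13598 genes were called (3 higher, 7 lower). Tested alone, the clusters of this class gave 9, 28, 12, 43, 63, 55 and 8 calls. Btaf1 rose from 28.7 and 29.1 to 62.7 and 64.5 CPM (log2 1.14, SE 0.08, edgeR adjusted p = 0.00371). Fkbp5 fell (-1.01, SE 0.09, 0.01004), and so did Hspa8 from 963 and 890 to 490 and 489 CPM (-0.92, SE 0.08, 0.01004), the protease gene Fap (-1.22, SE 0.13, 0.0331) and Nfkbia (-0.85, SE 0.10, 0.0466). Without OTUD1-/- 2 the calls of Hspa8, Fap and Nfkbia ended (adjusted p = 0.0671, 0.0741 and 0.113). The 5 calls outside the naming rule, named after their values were seen, were Ifi208 (-6.75, SE 0.32, 0.000376), with a mean under the rule's minimum, and the predicted genes Gm42031 (3.78), Gm49980 (1.41), Gm42047 (-0.78) and Gm16867, at 2.45 and 3.06 against 0 and 0 CPM. DESeq2 called 165, and the count was 578, 80, 97 and 10 without wild-type 1, wild-type 2, OTUD1-/- 1 and OTUD1-/- 2.

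In plasma cells 32 of 7580 genes were called (9 higher, 23 lower). Maml3 fell from 93.0 and 83.2 to 13.6 and 16.7 CPM (log2 -2.54, SE 0.28, edgeR adjusted p = 0.00304), against a rise in dendritic cells, a contrast that was not tested. Wfdc17, among the leading genes of a neutrophil cluster (-3.77, SE 0.28, 0.000316), and the decoy receptor Il1r2, a neutrophil marker (-3.32, SE 0.41, 0.00764), fell too. Whether RNA of neutrophils adds to these 2 falls was not tested. S100a4 rose (2.32, SE 0.34, 0.0193), a call that ended without wild-type 2 (adjusted p = 0.0770), and the basophil marker Hdc fell (-2.50, SE 0.41, 0.0376), ended without wild-type 2 (0.138) and OTUD1-/- 1 (0.164). DESeq2 called 94, and the count was 116, 54, 35 and 80 without wild-type 1, wild-type 2, OTUD1-/- 1 and OTUD1-/- 2.

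Several genes, chosen after their values were seen, lay on the same side of 0 in each class tested. Ifi208 was lower in 6 of 6 classes tested and called in 5, with log2 fold changes from -6.75 to -4.24. Fkbp5 was lower in 10 of 10 and called in 7 (-1.88 to -0.67, median -1.18), and Hspa8 was lower in 10 of 10 and called in 4 (-1.21 to -0.28). Btaf1 was higher in 10 of 10 and called in 5 (0.69 to 1.39), and Camk2b in 8 of 8 and called in 2 (0.47 to 1.83). The classes of a library share its preparation, so they are not independent of one another.

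**Figure D4:**
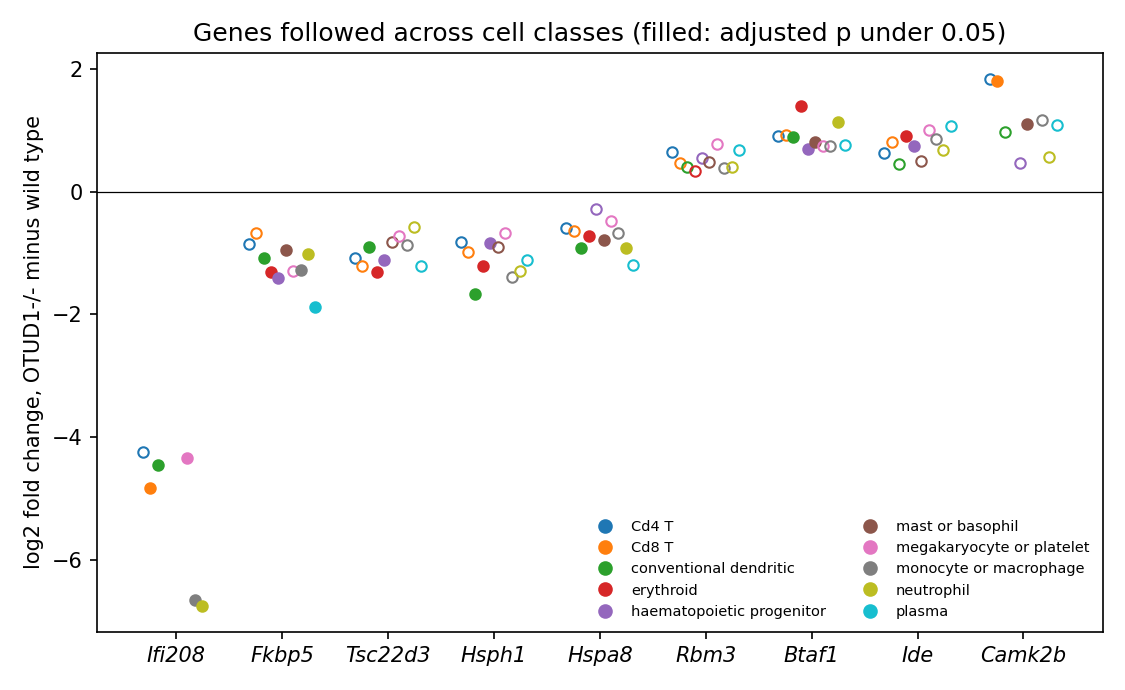
Log2 fold change, OTUD1-/- minus wild type (vertical axis), of 9 genes chosen after their values were seen, with 1 point per cell class and filled points for an adjusted p under 0.05. Ifi208 lies between -6.75 and -4.24 in the 6 classes where it was tested, and Fkbp5 below 0 and Btaf1 above 0 in 10 of 10 classes.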

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

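Tests of single clusters, crossed numbers and shares without unnamed clusters were chosen after the results were seen. Where a library is left out, the lone library of its group is assumed to vary like the other group. Called genes in Cd4 T, 0 with edgeR (812 at an unadjusted p under 0.05), were 22 with DESeq2, 211 without a gene filter, 2 with a gate at 2 UMIs and 0 to 471 with a library left out. In Cd8 T, 4 became 75 with DESeq2, 56 without a gene filter and 4 to 312 with a library left out. In the other classes 539 became 3965 without a gene filter and 1163 to 2767 with a library left out. The interaction, 0 with edgeR (425 at an unadjusted p under 0.05, 0 with DESeq2), was 44 without a gene filter and 1 to 460 with a library left out. Lists called, 20 in Cd4 T and 16 in Cd8 T, were 0 and 0 with an estimated correlation, 0 and 0 with fry, and 10 to 23 and 14 to 15 with a library left out. The adjusted p of the cell cycle list in Cd4 T ran from 4.85e-21 to 0.453 and turned to lower without OTUD1-/- 2. State genes with libraries apart, 6 of 14, were 3 not thinned and 2 at 1000 UMIs, and the difference turned to 0.277 percentage points for Tbx21 in Cd8 T at 1000 UMIs and to -0.587 for Pdcd1 in Cd8 T not thinned. The total of the other classes could not be formed with doublets kept or at resolution 0.5, where classes differ. Log2 fold changes of named genes in other settings kept their direction and side of the threshold in 1087 cases, lost the call in 213, gained it in 16 and turned in 5, and with a library left out in 422, 108, 10 and 4. Lists kept them in 528, lost the call in 82 and gained it in 10 cases, and with a library left out in 183, 43 and 19, with 1 turned, and state genes kept their value in 31 cases, moved in 9 and turned in 2. The cause of these moves was not tested.

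Class shares called, 4, were 1 with TMM factors, 2 without the erythroid, neutrophil and megakaryocyte classes, 2 without unnamed clusters and 0 to 1 with a library left out. The log2 fold change of erythroid, Cd8 T and plasma cells was 1.34, 1.19 and 1.30 with TMM factors, that of plasma cells 1.24 without those classes and 1.12 with the loose filter, and that of Cd8 T and plasma cells 1.05 and 1.14 without unnamed clusters, none called. With a library left out it was 2.53 to 3.46 for B, 0.89 to 2.03 for erythroid, 1.12 to 1.30 for Cd8 T and 0.72 to 1.69 for plasma cells. The log2 fold change of Otud1, never called, in Cd4 T was -0.0173 with the loose and -0.0283 with the strict filter, -0.0896 with doublets kept, -0.13 with a gate at 2 UMIs and -0.32 to 0.44 with a library left out, and there it was -0.0429 to 0.45 in Cd8 T, -0.19 to 0.50 in progenitors and 0.0286 to 0.92 in monocytes or macrophages. Iigp1 in platelets or megakaryocytes turned to 0.12 with the strict filter.

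The replicate numbers pair nothing the labels describe: deviations of same-numbered libraries correlated by -0.202 in Cd4 T, 0.422 in Cd8 T and -0.0227 to 0.318 in other classes. With the replicate number as a block, called genes were 1 in Cd4 T, 515 in Cd8 T and 2905 in the other classes, and class shares 0, at log2 fold changes of 2.95 for B, 1.45 for erythroid, 1.21 for Cd8 T and 1.21 for plasma cells. Crossed numbers gave 35 calls in Cd4 T.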

Other observations

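Of the tests below, those of genes and shares in single clusters, of genes followed across classes, of blocks of genes along the genome, of the Ifi200 family, of the second gene set, of the other glucocorticoid-induced genes and of isolation stress were chosen after the results were seen. The cluster of T cells led by Tcf7 and Il7r, genes of naive and memory T cells, made up 2.60% and 2.48% of cells in the wild-type and 5.47% and 6.86% in the OTUD1-/- libraries (log2 1.28, SE 0.51, edgeR adjusted p = 0.0626). The cycling cluster (1.31, SE 0.51, 0.0626) and the cytotoxic cluster (1.06, SE 0.50, 0.129) lay higher by similar amounts, so this is not particular to it, and none of the 3 passed. In the Tcf7 cluster Id3 rose (1.08, SE 0.16, adjusted p = 0.0191) and the receptors Slamf1 (-1.14, SE 0.18, 0.0261) and Cxcr4 (-0.94, SE 0.16, 0.0427) fell, among 21 called genes. In the cluster led by Gzma, Gzmb and Ccl5, genes of cytotoxic cells, the cytokine signalling inhibitor Cish fell (-1.24, SE 0.12, 0.00930) among 8 called genes. In the cycling cluster, led by histone genes, the survival gene Bcl2 fell (-0.80, SE 0.14, 0.0489) among 24, together with the neutrophil markers S100a8 and S100a9 (-1.46 and -1.46). The cluster led by Cd4 and Tnfrsf4 had 3 called genes, of which Camk2b rose (2.04, SE 0.24, 0.0432).

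The genes of this paragraph were picked one by one after their values were seen and stand for no group. The chaperone genes Hsph1 and Dnaja1 were lower in 10 of 10 classes and called in 3 and 1, and Hspa1b was lower in 5 of 5 with none called by edgeR, 4 of these at an unadjusted p under 0.05. The cold-inducible RNA-binding protein genes Rbm3 (0.33 to 0.78) and Cirbp (0.28 to 2.16) were higher in 10 of 10 and 9 of 9 classes with none called by edgeR, and 10 and 6 at an unadjusted p under 0.05. The complement gene Cfb was lower in 10 of 10 and called in 2, and the protease gene Ide was higher in 10 of 10 and called in 2. Ide lies on chromosome 19, 0.343 Mb from Btaf1, another gene higher in 10 of 10 classes.

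A gene was counted as shifted alike if tested in at least 8 classes and on the same side of 0 in each. It also needed an unadjusted p under 0.05 in at least 5. With libraries split by genotype 138 genes did so, against 8 and 1 in the splits that put a wild-type with an OTUD1-/- library. A group difference widens the spread within the mixed splits, so 8 and 1 are no chance level. The split cannot tell genotype from anything else the 2 libraries of a group share. In wild-type Cd8 T cells the median level of the 138 genes, relative to non-T cells, was 15.3 times that of neutrophil markers. This argues against RNA carried from non-T cells into Cd8 T cells for the set as a whole. Such carry-over stays open for the 34 genes at up to 2 times. The ratio cannot show RNA carried from T cells into other classes, which stays open. For a segment of another strain around Otud1, 3 of the 138 genes lay within 20 Mb of it (random draws: median 3, 95th percentile 6). Of the 43 genes of a second set, which asks for fewer classes and a minimum size, 0 did (median 1, 95th percentile 3). Genes near Otud1 were thus not in excess. A segment that moved only a few genes need not pass these percentiles and stays open. For blocks elsewhere, 40 of the 138 had a neighbour of the set within 2 Mb (95th percentile 55). Of the 43, 17 did (95th percentile 10, permutation p = 0.0003). Histone and stefin genes lie side by side in any mouse. The antibody genes Igha and Ighg2c share 1 locus on chromosome 12, and Gm49838 lies within the span of Fkbp5. Such neighbours can count toward the 17 without a block, so this excess does not show blocks. Btaf1 and Ide of the first set, 0.343 Mb apart on chromosome 19, are of none of these kinds. That set had no excess of neighbours (median of draws 43). Blocks may or may not explain the remaining neighbours. A weaker interferon response at the Ifi208 locus is argued against by the 12 other Ifi200 genes in monocytes or macrophages, with a median of -0.37 beside -6.66 for Ifi208, and a donor sequence difference in Ifi208 and the genotype itself stay open, untested.

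Of the glucocorticoid-induced genes, 5 picked for being lower in the OTUD1-/- libraries were Fkbp5 and Tsc22d3 (lower in 10 of 10 classes, called in 7 and 3), Zbtb16 (6 of 6, called in 2), and Klf9 (7 of 7) and Ddit4 (9 of 9), called in none by edgeR with 5 and 4 classes at an unadjusted p under 0.05. In wild-type Cd8 T cells the median of these 5 stood at 12.005 times the relative level of neutrophil markers. This argues against RNA carried from non-T cells into Cd8 T cells. The ratio cannot show RNA carried from T cells into other classes, which stays open. Stress of cell isolation stays open: the stress list had a negative median in 9 of 10 classes, which goes with it, and although that list fell by less than the 5 genes, or not at all in basophils, in 10 of 10 classes, genes picked for being low make this comparison uninformative. Lower exposure to glucocorticoids, a candidate explanation, cannot be told apart from none: over 10 further induced genes, of which Per1 and Il1r2 had already been seen lower, the median was negative in 7 of 10 classes, and without Per1 and Il1r2 in 6. A genotype effect stays open and was not tested apart from these.

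Markers of neutrophils, macrophages and red cells shifted inside T cells, as given beside the gene lists. Over 93 marker genes of non-T classes, log2 fold changes in Cd8 T cells followed those of all cells outside the T classes (Spearman 0.831). In Cd4 T the value was 0.735 over 70 genes, and genes are not independent replicates. RNA carried over from other cells would give such an order. The sizes differed: medians in Cd8 T and in the other cells were -0.77 and -0.34 for neutrophil markers. They were -0.53 and -0.35 for monocyte or macrophage markers, and 0.33 and 1.35 for erythroid markers. Keeping predicted doublets moved the neutrophil marker median in Cd8 T by 0.400, from -0.77 to -0.37, with a rise of their level by 1.13%, and since no direction had been set beforehand, doublets cannot be told apart from other causes. A change of these genes within T cells themselves was not tested.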
